A study of Solanum lycopersicum with 26 samples.

How the data were processed

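Messenger RNA was sequenced from the pericarp, the fleshy wall of the fruit, of glasshouse tomatoes (Solanum lycopersicum, variety Moneymaker) at 9 stages of development. Per the labels' protocols, fruit came from 3 trusses, seeds and the gel around them were taken out, and 8 internal standards were added as RNA extraction began, before stranded poly(A) libraries were made. A stage is named by the letter F and the days post anthesis in the library titles: F8, F15, F21, F28, F34, F41, F49, F50 and F53. The day label of the F41 libraries gives 42. Each stage had 3 libraries except F49, of which 2 were analysed here, which made 26 libraries. Whether a replicate number stands for a truss is not stated, so p-values measure the spread between these libraries.

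The authors deposited read counts per gene and library, and also per library and sequencing lane. For each library the counts of its 2 lanes summed to the library's count, except in 60 of 902876 values, each of which differed by 1 read. Per the submitters' processing notes, Trimmomatic 0.32, STAR 2.4.2a, HTSeq 0.6.1 and Cufflinks 2.2.1 were used, with no role given. The genome build and the annotation are not given in the sources used here. The deposited TPM values, transcript shares scaled to a fixed total, summed to the same total in every library with the internal standards included, and 2 genes held no TPM. The third deposited quantity was the concentration in fmol of transcript per gram fresh weight. In each library it was a power function of the TPM value, with an exponent between 0.747 and 0.994 and a largest residual of 1.8e-13 on the natural log scale. The calibration is not stated. Of the standards, RNA_SPIKE6-EC13 had reads in 19 libraries, RNA_SPIKE7-EC18 in 4 and RNA_SPIKE8-EC5 in 0. The deposited concentrations of the standards themselves varied between libraries. They ranged from 267 to 762.6 fmol per gram for RNA_SPIKE1-EC2 and from 3.047 to 6.766 for RNA_SPIKE3-EC3. The source of this spread was not tested. An exponent under 1 compresses the differences between genes and varies between libraries, so a concentration ratio depends on the library's own exponent.

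The count table held 34727 gene rows and 8 rows of internal standards, which were kept out of library sizes and gene tests and took 0.181 to 3.94% of the counted reads. Gene reads per library lay between 14447700 and 39869200. A library's 2 lanes differed by 1.005 to 1.138 chi-square per degree of freedom over genes with at least 20 reads. Libraries of a stage differed by 15.6 to 142, so no library was a copy of another of its stage. Libraries of different stages were not compared in this way. Libraries of F8 to F34 and F41 replicate 1 ran on lanes 3 and 4, and all others on lanes 1 and 5. Lane pair therefore followed the stage outside F41.

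Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, the low-count filter filterByExpr and 1 fit over all libraries, with the stage as the only term. The filter kept 20990 genes. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 change was its size divided by the square root of F. Concentrations were tested with limma 3.58.1 (trend) on log2 of the value plus a pseudocount of 0.00824 fmol, the 5% quantile of values above 0, so fold changes of low genes are understated on that scale. Total concentrations were compared with exact two-sided permutation tests between 2 stages, where 3 libraries against 3 cannot give a p below 0.1, and with 100000 resamples over the 9 stages.

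Of 35 gene lists fixed before the data were examined, 27 were to be matched to gene descriptions. Neither the deposited tables nor the reference table (assembly SLM_r2.1) paired the gene identifiers with descriptions: 0 identifiers matched, so those lists were not run and genes are given by identifier. The other 8 lists, of 89 loci, were written as identifiers from general knowledge of the loci, and their membership could not be checked against a table here. Lists were tested with camera (preset correlation 0.01, and again with an estimated correlation), adjusted over the lists of a comparison. By the rule fixed with the lists, the genes printed are at most 2 that rose most and 2 that fell most in each of F34 vs F8 and F53 vs F41, among called genes with a mean log2 CPM of at least 4 and no overlap between the libraries of both stages. Solyc11g051210.1 was chosen after its values were seen.

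The tests were run on simulated data first, with 200 changed genes drawn on the means and sizes of the real libraries. In F34 vs F8 (20320 genes) edgeR recovered 91.3% of the 4-fold changes, 44% of the 2-fold changes and 10.71% of the 1.5-fold changes. In F53 vs F41 (20280 genes) these were 91.8%, 40.3% and 8.333%, and in F28 vs F21 (20320 genes) 83.33%, 59.15% and 19.3%. The limma test of concentrations recovered 32.88% of the 4-fold and 4.478% of the 2-fold changes in F34 vs F8 (20990 genes), and 36.51% and 1.266% in F53 vs F41. In the real data edgeR called 10823 genes in F34 vs F8 and 13123 in F53 vs F41, far more than the 200 changed here. The adjusted threshold was therefore stricter in the simulation, and these recoveries may be too low for those comparisons. In F28 vs F21 edgeR called only 4 genes in the real data. There the threshold was more lenient in the simulation, and the recoveries may be too high. Alternatives were DESeq2 1.42.0, its size factors in edgeR, library totals alone, other filters, the replicate number or the lane pair as a term, fits of 2 stages alone, other pseudocounts and each library left out. Added after the data were seen were fits without F53 replicates 2 and 3 and F41 replicate 1, the genes changed in both F34 vs F8 and F53 vs F41 without these libraries, glycoalkaloid genes without each of them, totals without Solyc11g051210.1, and scaling to the internal-standard reads. Plots were drawn with matplotlib 3.10.9.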

Results

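The series measured mRNA in tomato pericarp from the young, growing fruit at F8 to the late stage F53, and its design text names absolute mRNA concentration as the quantity sought. The 26 libraries held 14447700 to 39869200 gene reads each, and 20990 genes entered the tests. The principal components of log2 CPM spread the stages along PC1, which held 67.7% of the variance, from F8 at the low end to F49, F50 and F53 at the high end, and set F8 and F15 apart from F21 to F41 along PC2, with 15.2%. F41 replicate 1 lay at -63.7 on PC1, between the F21 and F34 libraries, while F41 replicates 2 and 3 lay at 5.96 and 11.8. F41 replicate 1 was also the only F41 library on lanes 3 and 4.

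**Figure D1:**
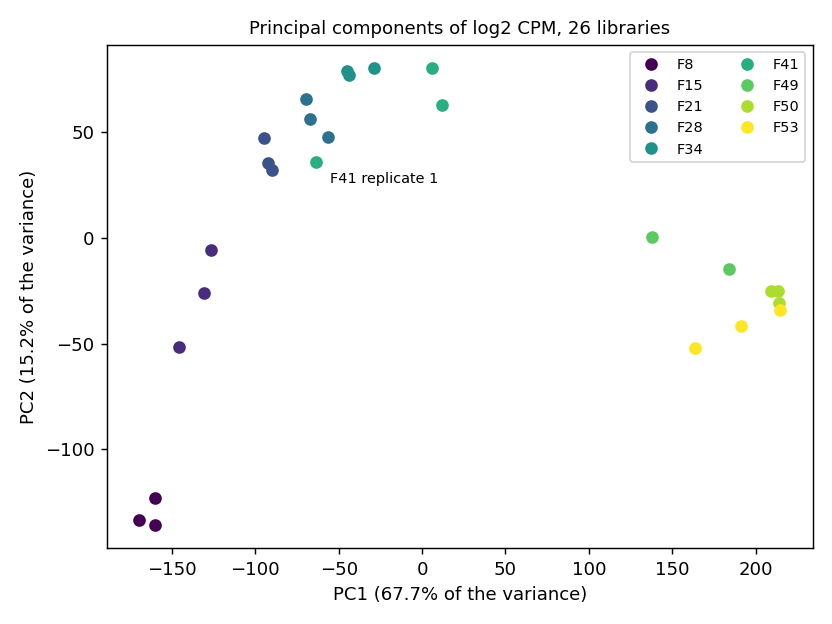
Principal components of log2 CPM, with PC1 (67.7% of the variance) on the x axis and PC2 (15.2%) on the y axis; each point is 1 library, coloured by stage. F41 replicate 1 sits at -63.7 on PC1 and both other F41 libraries at 5.96 and 11.8.

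Over the 9 stages, 18509 genes changed (88.18% of those tested; edgeR quasi-likelihood test, adjusted p under 0.05). On the CPM scale, 5259 of them (28.4%) were highest at F8, and 7900 (42.68%) were highest at F49, F50 or F53. On the scale of fmol per gram fresh weight, 16374 (88.5%) were highest at F8, so the stage of the highest level depended on whether a gene was compared with the rest of the transcriptome or with the mass of fruit.

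Total mRNA per gram was highest in the young fruit. The concentration summed over genes was 232 ± 73.5 pmol per gram fresh weight at F8 (SD, n = 3), 107 ± 7.07 at F15 (n = 3) and 33.2 ± 8.07 at F21 (n = 3). It then stayed between 23.5 ± 5.15 at F34 (n = 3) and 36.3 ± 0.193 at F49 (n = 2), with 23.9 ± 1.59 at F53 (n = 3). Over the 9 stages, totals differed by more than the spread between libraries (F = 28.22, p = 2e-05, permutation test). At F34 the total was 9.69-fold lower than at F8, each F34 library lying below each F8 library (3 of 3), with p = 0.1 in the exact two-sided permutation test, the smallest that 3 libraries against 3 can give. Between F41 and F53 the log2 difference was -0.33 (exact permutation test, p = 0.4), and it was 0.23 when gene reads were divided by internal-standard reads (p = 0.6), so no direction was resolved there.

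**Figure D2:**
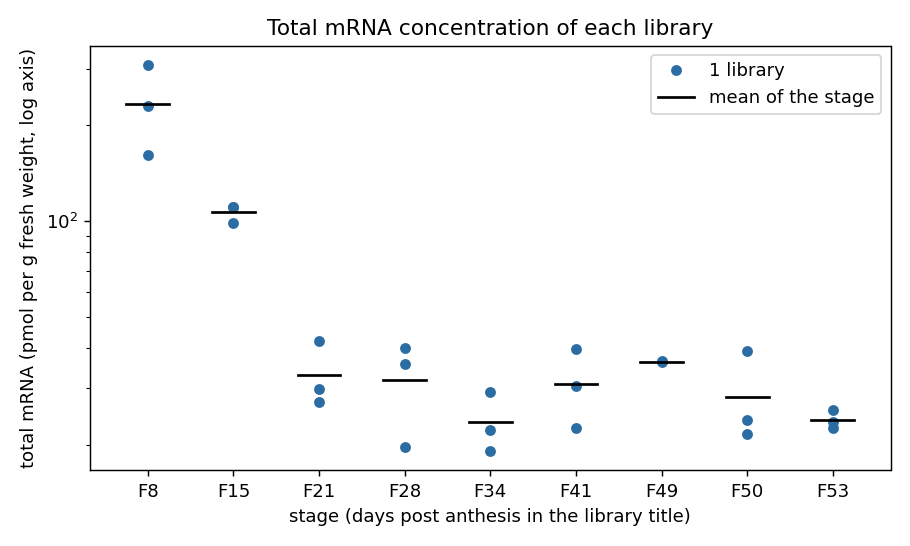
Total mRNA concentration in pmol per gram fresh weight on a log axis (y) against stage (x); points are libraries and bars are stage means. The F8 libraries average 232 and the F34 libraries 23.5.

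F34 was compared with F8 to ask how the pericarp transcriptome differed between early and late growth. Relative to the other genes, the ripening regulators, transcription factors and a DNA demethylase known to control the onset of ripening, rose before ripening: 7 of 9 members rose, 0 fell, and the median log2 change was 2.72 (range 0.42 to 9.23; adjusted p = 5.33e-06 with camera, and 0.0157 with an estimated correlation). The largest changes among the regulators, 9.23 and 4.36, were of genes near the floor, at 0 and 0.0681 CPM at F8 and 3.30 and 1.52 CPM at F34. Of the 21 genes of ethylene synthesis and perception, the hormone pathway of climacteric ripening, 9 rose and 0 fell (median 0.57). That list's adjusted p was 0.0173, and its adjusted p was 0.229 with an estimated correlation. The genes of steroidal glycoalkaloids, bitter defence compounds of green fruit, went the other way, with 9 of 10 fallen and 1 risen (median -4.69, lowest -11.49). Their adjusted p was 0.0453, and 0.482 with an estimated correlation; over the other alternatives it lay between 0.0185 and 0.103, and it passed 0.05 without F34 replicate 2 (0.103), F34 replicate 1 (0.0691) or F8 replicate 3 (0.0505) and with the size factors of DESeq2 (0.0527).

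The other lists moved in both directions. In the carotenoid pathway, which makes the pigments of plastids, 9 of 18 genes rose and 5 fell (median 0.34, adjusted p = 0.149). In fruit softening, which holds cell wall enzymes, 4 of 10 rose and 2 fell (adjusted p = 0.0987; 0.0458 without F34 replicate 3, and up to 0.45 over the alternatives), and in aroma volatiles 2 of 4 rose and 1 fell (adjusted p = 0.0987). Sugar and acid metabolism had 3 risen and 1 fallen of 11, with a median of -0.23 against an upward camera direction (adjusted p = 0.463), and chloroplast development and chlorophyll loss had 1 risen and 1 fallen of 4 (adjusted p = 0.862). Adjusted over the list alone, 8 ripening regulators rose in place of 7, and the counts of the other 7 lists did not move.

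Among single genes, Solyc07g064170.2, a member of the fruit softening list, rose from 11.8 ± 9.26 CPM at F8 to 6335 ± 1620 at F34 (SD, n = 3 each; log2 change 9.07, SE 0.793, edgeR adjusted p = 2.56e-08). Solyc10g080210.1, of the same list, had 2 reads over the F8 libraries and 2203 over the F34 libraries, a ratio of 960 with a counting interval of 265 to 7930 (95%, exact binomial). The interval covers counting alone and not the spread between libraries: the F34 reads were 397, 1803 and 3 in replicates 1, 2 and 3. Its log2 change was 9.65 (SE 2.7, adjusted p = 0.0052), or 7.65 without F34 replicate 2, and on the fmol scale the adjusted p was 0.0842 (limma), against 1.18e-05 to 0.0265 under the other alternatives. Solyc09g091510.2 fell from 443 ± 183 to 2.56 ± 1.71 CPM (n = 3 each; log2 change -7.44, SE 0.903, adjusted p = 1.22e-06), and Solyc07g007250.2 from 5106 ± 1442 to 47.9 ± 1.90 CPM (n = 3 each; log2 change -6.74, SE 1.31, adjusted p = 0.000233). In all, 10823 genes changed, of which 4823 rose and 6000 fell; with the filter of at least 50 reads in 3 libraries, 4755 rose and 4604 fell.

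On the scale of concentration the same comparison was almost wholly downward. With limma on log2 fmol per gram, 19163 genes fell and 202 rose from F8 to F34, with a median change of -3.52, or 11.5-fold lower. Of the 4823 genes that rose relative to the other genes, 3906 fell in concentration and 189 rose. The median of the ripening regulators was -1.02 and that of the ethylene list -2.96 on this scale, the reverse of their relative direction, and the medians of aroma volatiles (-1.28), the carotenoid pathway (-3.30), fruit softening (-3.10) and chloroplast development (-2.91) also lay below 0. When each library was centred on its median, 5970 genes rose and 4070 fell.

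F53 was compared with F41 to describe the passage from the full-grown fruit to its last sampled stage. A group of 3 lists rose also with an estimated correlation. In the first, 8 of 9 ripening regulators rose and 0 fell (median log2 change 3.21; adjusted p = 1.5e-05 with camera, 0.0155 with an estimated correlation). In the carotenoid pathway 11 of 18 genes rose and 3 fell (median 1.34; adjusted p = 4.11e-07, and 0.0303 with an estimated correlation). In ethylene synthesis and perception 13 of 21 rose and 4 fell (median 1.04; adjusted p = 0.000603, and 0.0443 with an estimated correlation). Fruit softening had 7 of 10 risen and 2 fallen, with a median of 4.70. Its adjusted p was 0.0288, the adjusted p with an estimated correlation was 0.206, and the adjusted p without F41 replicate 3 was 0.0651, the range over the alternatives being 0.00426 to 0.206. Of the 4 aroma volatile genes 3 rose (median 3.57). Their adjusted p was 0.0499, and 0.102 with an estimated correlation. It was 0.1 without F41 replicate 3, 0.0596 without F53 replicate 2 and 0.0607 with the replicate block. The lowest over the alternatives was 0.0289.

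Genes of sugar and acid metabolism divided, with 4 of 11 risen and 5 fallen (adjusted p = 0.703), and chloroplast development and chlorophyll loss had 2 of 4 risen and 1 fallen (adjusted p = 0.703). Steroidal glycoalkaloid genes had 1 of 10 risen and 5 fallen (median -1.74, adjusted p = 0.435). F53 replicates 2 and 3 held transcripts abundant at F8 at a median of 0.787% and 0.346% of their F8 level, against 0.00431% in F53 replicate 1. F41 replicate 1 held them at 3.36%, against 0.0518% and 0.0252% in F41 replicates 2 and 3. Its share was less even between genes, with a median absolute deviation of the log2 share of 0.712. That deviation was 0.206 and 0.287 in F53 replicates 2 and 3. The libraries in doubt were F53 replicates 2 and 3 and F41 replicate 1. Without these 3 libraries glycoalkaloid genes had 0 risen and 5 fallen (median -4.47, adjusted p = 0.0187, and 0.373 with an estimated correlation). Without F41 replicate 1 alone, 0 rose and 3 fell (median -0.61, adjusted p = 0.695). F53 replicates 2 and 3 were doubted for transcripts abundant at F8, of which this list holds some, so these values are no independent test of a fall. Adjusted over the list alone, 5 sugar and acid genes rose in place of 4, and the counts of the other 7 lists did not move.

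**Figure D3:**
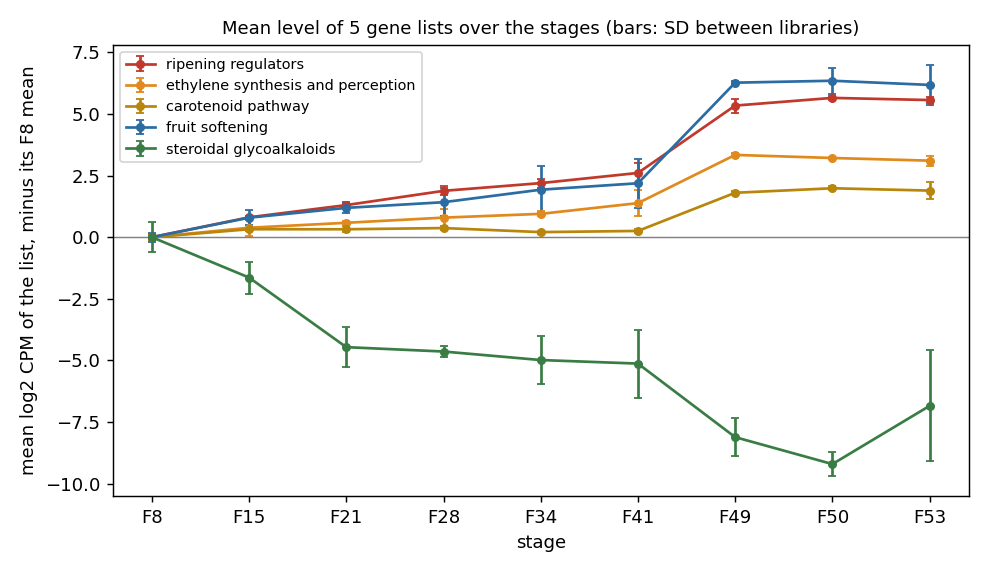
Mean log2 CPM of 5 gene lists, less the F8 mean of the list (y), against stage (x); points are means over the libraries of a stage and bars are SD (n = 3; n = 2 at F49). Fruit softening reaches 6.27 and ripening regulators 5.34 at F49, while steroidal glycoalkaloids stand at -9.21 at F50 and -6.85 at F53.

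Solyc10g080210.1, of the fruit softening list, rose from 7.88 ± 8.50 CPM at F41 to 16300 ± 4883 at F53 (SD, n = 3 each; log2 change 11.03, SE 2.35, edgeR adjusted p = 0.000399), and was higher still at F50, at 29060 ± 3806 (n = 3). Solyc09g066150.1 rose from 21.9 ± 6.28 to 2371 ± 476 CPM (n = 3 each; log2 change 6.76, SE 0.693, adjusted p = 6.06e-08). Solyc02g065780.1 fell from 131 ± 21.7 to 0.617 ± 0.314 CPM (n = 3 each; log2 change -7.84, SE 0.367, adjusted p = 3.5e-12), and Solyc03g020060.2 from 111 ± 92.3 to 0.564 ± 0.418 CPM (n = 3 each; log2 change -7.62, SE 0.777, adjusted p = 5.64e-08). In all, 13123 genes changed, 6474 of them up and 6649 down. In concentration, 2024 genes rose and 2432 fell (limma), with a median change of 0.08. The exponents behind the concentrations differed within both stages. At F41 the exponent was 0.785 in replicate 1, against 0.984 and 0.994 in replicates 2 and 3. At F53 it was 0.747 in replicate 3, against 0.945 and 0.951 in replicates 1 and 2. How far this moved the counts was not tested. Which side was larger depended on single libraries and on the lane pair: 4226 rose and 1650 fell without F41 replicate 1, 4224 rose and 1653 fell with the lane pair as a term, and 1155 rose and 3317 fell without F41 replicate 2. Without F53 replicates 2 and 3 and F41 replicate 1, 1413 rose and 1093 fell, and with only the 2 stages fitted 613 rose and 611 fell.

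Consecutive stages were compared to place these changes in time. The transcriptome moved at the start of the series and again between F41 and F49. From F8 to F15, 1881 genes rose and 2265 fell, and 6 of 9 ripening regulators were among those that rose (adjusted p = 0.000661 with camera; the adjusted p was 0.0747 with an estimated correlation). In the carotenoid pathway 5 of 18 rose (adjusted p = 0.0362, and 0.408 with an estimated correlation). From F15 to F21, 450 rose and 534 fell, but rises were the larger number with library totals alone (564 against 336), with the filter of at least 50 reads (510 against 467) and without F21 replicate 1, 2 or 3 (220 against 113, 243 against 160 and 251 against 200). Glycoalkaloid genes fell as a list there (3 of 10 fallen, median -2.68, adjusted p = 0.000154, and 0.298 with an estimated correlation), and ripening regulators rose (1 of 9 risen, median 0.57, adjusted p = 0.00547, and 0.217 with an estimated correlation). From F41 to F49, 7 days apart by label, 4701 rose and 5120 fell, or 3039 and 6491 with library totals alone. Rises were the larger number without F49 replicate 3 (3176 against 2997) and with only the 2 stages fitted (2745 against 2702). Of the lists, 7 of 9 ripening regulators, 13 of 21 ethylene genes, 10 of 18 carotenoid genes and 7 of 10 softening genes rose, and 0, 3, 2 and 1 fell. The camera adjusted p values of these 4 lists were 1.39e-07, 8.56e-07, 2.45e-09 and 0.00254, and 0.00428, 0.00672, 0.00672 and 0.066 as adjusted p with an estimated correlation. Of 4 aroma volatile genes 2 rose (adjusted p = 0.0352, and 0.066 with an estimated correlation). In the same interval 8 of 10 steroidal glycoalkaloid genes fell and 0 rose (median -4.49, adjusted p = 0.0608). Without F41 replicate 1, 5 fell (median -2.73, adjusted p = 0.0724), and without F53 replicates 2 and 3 as well 6 fell (median -2.76, adjusted p = 0.022); with an estimated correlation the adjusted p was 0.524 in the fit of all libraries and 0.408 without these 3. From F49 to F50, 1 day apart, 381 genes rose and 1207 fell, or 197 and 1300 with library totals alone.

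Between these times few genes passed the test. From F21 to F28 edgeR called 4 genes, from F28 to F34 it called 2 and from F34 to F41 it called 5, while DESeq2 called 66, 36 and 135. As lists, ripening regulators passed camera upward in each of these intervals (adjusted p = 0.000985, 0.035 and 0.0402), aroma volatiles from F28 to F34 (adjusted p = 0.00943), and the ethylene and chloroplast lists from F34 to F41 (adjusted p = 0.0385 and 0.0402). None passed with an estimated correlation, the lowest adjusted p being 0.0522. Of the ripening regulators 0 of 9 were called in each interval. Their median log2 changes were 0.28, -0.02 and 0.18, so from F28 to F34 the median went against the upward camera direction. At an unadjusted p under 0.05 the numbers of genes were 1835, 1301 and 1570. Over the longer step from F21 to F34, 500 genes rose and 665 fell, so the small counts do not show that the fruit stood still. The F34 to F41 count was 681 without F41 replicate 1, and 0 without any 1 of the other 5 libraries. From F50 to F53, 31 genes rose and 56 fell. This balance turned to 35 risen and 14 fallen with library totals alone, 285 and 145 with DESeq2, 172 and 61 without F53 replicate 1, and 109 and 23 without F53 replicate 3. Glycoalkaloid genes stood higher at F53 than at F50 as a list (median 4.64, camera adjusted p = 1.73e-07, and adjusted p = 0.211 with an estimated correlation). Of these, 0 of 10 rose with adjustment over all genes, and 6 when adjusted over the list alone. Their levels were low: all but a single member lay between 0.655 and 43.0 CPM at F53, against 63.9 to 10550 at F8. The summed list stood at 4.45 to 5.29% of its F8 level in the F50 libraries and 5.1 to 6.85% in the F53 libraries. That single member, at 854 CPM, made most of the sum at F53. With 0 of 10 genes risen in each fit, the list still stood higher without F53 replicate 2 alone (median 3.57, adjusted p = 0.00046, and 0.375 with an estimated correlation) and without F53 replicate 3 alone (median 4.68, adjusted p = 6.73e-05, and 0.29 with an estimated correlation). In the fit without both and F41 replicate 1, which left 1 F53 library, it did not (median 0, adjusted p = 0.811), as follows in part from the choice of libraries that held transcripts abundant at F8.

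Several interval counts rested on single libraries. The F21 to F28 count of 4 became 0 or 1 without any 1 of its 6 libraries, and the F28 to F34 count of 2 became 0 without F28 replicate 1, F28 replicate 2 or F34 replicate 2. The F8 to F15 count of 4146 became 2514 without F8 replicate 1 and 2179 without F15 replicate 2. The F15 to F21 count of 984 became 125 without F15 replicate 1, 388 without F15 replicate 3, and 333, 403 and 451 without F21 replicates 1, 2 and 3. The F41 to F49 count of 9821 became 6173 without F49 replicate 3. The F49 to F50 count of 1588 ranged from 181 without F49 replicate 2 to 2383 without F49 replicate 3, and was 876 and 710 without F50 replicates 2 and 3. The F50 to F53 count of 87 became 10, 45 and 37 without F50 replicates 1, 2 and 3, and 233, 48 and 132 without F53 replicates 1, 2 and 3.

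**Figure D4:**
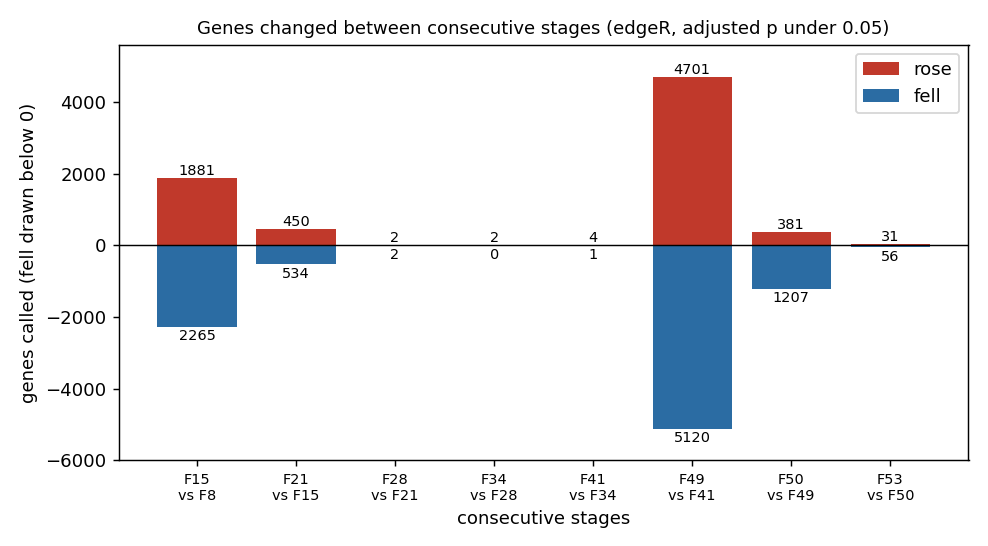
Number of genes called by edgeR between consecutive stages (y; genes that fell are drawn below 0) for each interval (x). The interval from F41 to F49 has 4701 genes up and 5120 down, and the interval from F28 to F34 has 2 up and 0 down.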

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

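No rule for single outlying libraries was applied within the stages of 2 or 3 libraries, and the series has no second tissue or genotype in which a contrast could be repeated. The test of TPM per count was chosen after the values were seen. In the deposited TPM table, which was not itself tested but from which the concentrations derive, Solyc11g051210.1 took up to 35.4% of the TPM of a library and at least 3.27%, from only 44 to 547 counted reads (2.51 to 24.1 CPM). Its share of the summed fmol was at most 32.0%, in F50 replicate 3. Its TPM was 7277 to 30470 times its CPM, while the median gene with at least 20 reads in every library had a ratio of 0.562. The highest ratio of another such gene was 5180. A fixed transcript length was predicted to give a ratio as steady across libraries as that of genes with similar read numbers. The coefficient of variation of Solyc11g051210.1 was 0.364, above the 99th percentile of 0.312 over 3673 genes of similar read number. Those genes were not matched for length or for the size of the ratio, so the test cannot decide whether a very short gene model is the cause. A further 22 genes had a TPM of at least 100 in a library with under 10 counted reads, the highest 4637.4 TPM with 0 counted reads in any library, so reads entered the TPM of some genes without entering the counts. Whether this holds for Solyc11g051210.1 stays open without the alignments, and no biological explanation was tested. The total at F34 was 10.5-fold below that at F8 without this gene, against 9.69-fold with it.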

How the results depend on the processing

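The replicate numbers did not pair the libraries: deviations from the stage mean correlated at -0.0238 on average over 100 pairs of the same number, 19 of these pairs were over 0.1, and 3 of 26 libraries correlated best with their own number. With the replicate block, F28 vs F21 and F41 vs F34 had 0 calls each, F34 vs F8 had 10570 and F53 vs F41 had 12879, and no other count moved by over 1.5 times; the aroma volatiles of F53 vs F41 were no longer past the threshold (adjusted p = 0.0607). In every setting below the cause was not tested unless fewer libraries or a stricter rule is its construction. Size factors of DESeq2 in edgeR gave 0 calls in F28 vs F21 and F41 vs F34. Library totals alone gave 22 in F41 vs F34 and 49 in F53 vs F50. With the lane pair as a term, F28 vs F21 had 14 and F34 vs F28 had 18, or 11 and 12 with the replicate block as well. F41 vs F34 had 1 in both fits. There the lane term leaves F41 replicate 1 alone to be set against F34, so this is no stage comparison corrected for lane. Fitting only the 2 stages compared gave 0 in F28 vs F21, F41 vs F34 and F53 vs F50, 5447 in F49 vs F41, 699 in F50 vs F49, and 1224 for concentrations in F53 vs F41. Asking for at least 2-fold gave 6611 in F34 vs F8, 8424 in F53 vs F41, 2406 in F15 vs F8, 605 in F21 vs F15 and 6046 in F49 vs F41. DESeq2 gave 1498 in F21 vs F15, 66 in F28 vs F21, 36 in F34 vs F28, 135 in F41 vs F34 and 430 in F53 vs F50. The doubted libraries left out (F53 replicates 2 and 3 and F41 replicate 1, chosen after seeing the data) gave 32 in F53 vs F50, 797 in F41 vs F34 and 2506 for concentrations in F53 vs F41.

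Centring each library on its median gave 10040 calls for concentrations in F34 vs F8 and 10588 in F53 vs F41. On the fmol scale 16374 genes were highest at F8. The medians of the ripening regulators (-1.02) and of the ethylene list (-2.96) in F34 vs F8 reversed there, and the total of F53 vs F41 reversed to 0.23 as gene reads per internal-standard read, an alternative chosen after seeing the data.

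Leaving out each library in turn gave 9408 to 10103 in F34 vs F8, 11758 to 12660 in F53 vs F41, 2179 to 3314 in F15 vs F8, 125 to 855 in F21 vs F15, 0 to 1 in F28 vs F21, 0 to 2 in F34 vs F28, 0 to 681 in F41 vs F34, 6173 to 9659 in F49 vs F41, 181 to 2383 in F50 vs F49 and 10 to 233 in F53 vs F50. In a stage left with 1 library that library is assumed to vary like the other stages. Of all other values, 252 of single genes and lists kept their direction and their side of the threshold, and 217 of counts and totals stayed the same by size, a count within 1.5 times. Among 127 such counts with directions, the larger of risen and fallen turned in 7. In F21 vs F15 it turned to 564 risen and 336 fallen with library totals alone and 510 and 467 with at least 50 reads, and in F34 vs F8 to 4755 and 4604 with at least 50 reads. For concentrations in F53 vs F41 it turned to 4226 and 1650 without F41 replicate 1. It turned to 4224 and 1653 with the lane pair, which sets that same library aside in this contrast. It also turned to 2151 and 1768 without F53 replicate 2, and to 1819 and 1782 with 10 times the pseudocount. On the fmol scale 7 list medians moved by more than 1 SD of that list's median log2 CPM between the libraries of a stage (the larger SD of both stages), and 5 of these changed sign: aroma volatiles, carotenoid pathway, fruit softening and chloroplast development fell below 0 in F34 vs F8, and sugar and acid metabolism rose to 0.19 in F53 vs F41. In all, 13 single-gene or list values were no longer past the threshold and 2 newly past it. Of the latter, the glycoalkaloids of F53 vs F41 without the doubted libraries are no independent test, as F53 replicates 2 and 3 were chosen by transcripts abundant at F8. Library totals alone moved the median change of F53 vs F41 to -0.17 and its share of risen calls from 49.33 to 42.14%. In simulations at the sizes and numbers of these libraries, edgeR recovered 10.71, 8.333 and 19.3% of 1.5-fold changes in F34 vs F8, F53 vs F41 and F28 vs F21, and other depths were not simulated. The alternatives of lists matched by description were not run.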

Other observations

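Growth and ripening changed many genes in common, no more than independent lists would share. A hypothesis written before the test was that genes changed in growth turn back in ripening. F34 vs F8 and F53 vs F41 share no library. Both were taken from the edgeR calls, relative to the other genes, and the fmol scale was not tested for this. Of the genes tested, 6744 changed in both, against 6767 for independent lists. Of the 6744, 38.3% went in opposite directions, against 49.6% from the directions of each comparison alone. A general turning back was thus not found on the relative scale. F41 replicate 1 and F53 replicates 2 and 3, doubted below, enter this comparison. Without all 3, a choice made after the data were seen, 40.5% of 5339 shared genes went in opposite directions, against 49.6% from the directions alone; without 1 of them at a time the share was 37 to 41.2%, against 49.2 to 50%. Genes that fell in growth and rose in ripening numbered 1069 (1851 for independent lists), while 2460 fell in both (1901 for independent lists) and 1698 rose in both (1488 for independent lists).

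The tests of F41 replicate 1 and of the F53 libraries were chosen after these patterns were seen, and the tests on splits of the libraries were planned. F41 replicate 1 stood apart from the other F41 libraries. On an axis from F21 (0) to F34 (1), with the libraries that define it held out in turn, it lay at 0.763, within the F34 libraries (0.616 to 0.929), and F41 replicates 2 and 3 lay at 1.36 and 1.19. Over the 7863 genes that are not higher at F8 than at F34 it still lay at 0.85, against 1.38 and 1.22. This argues against F8-like RNA in that library as the whole cause. It does not reach RNA of F15, F21 or F28, which could move the library back on this axis over the same genes. On PC1 the library lay at -63.7, among the F28 libraries (-69.6 to -56.6), which stood at 0.388 to 0.652 on the axis. Fruit at an earlier point of development, by growth or by label, may account for the position; the lane pair cannot be told apart from it, because the other F41 libraries ran on the other lanes and no other stage spans both.

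F53 replicates 2 and 3 held transcripts of young fruit. Over 24 genes chosen for at least 500 CPM at F8 and under 1 CPM in each F50 library, F53 replicate 2 stood at 0.787% of the F8 level (quartiles 0.697 and 0.874%) and F53 replicate 3 at 0.346% (0.309 and 0.414%). The median absolute deviation of the log2 share was at most 0.287 in both, a nearly constant share as carry-over of F8-like RNA or library material would give, and this is a candidate explanation for those genes. In F53 replicate 2 it does not reach the other part of the pattern: 70.8% of the 89 genes of F53 replicate 2 at 16 times their F50 level or more exceeded 4 times the level that this share of F8 gives. In F53 replicate 3 it was 8 of 21 genes (38.1%), which leaves the same question open there. For the genes over that level, another admixture and differences between fruit of 1 stage stay open and were not tested. By the column names, each F53 library carried the same sequencing index as the F8 library of its replicate number, on other lanes. F53 replicate 1 shared its index in this way too, and stood at 0.00431% of the F8 level over the 24 genes. Whether the shared index bears on the F8-like transcripts was not tested.

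The count of genes changed over the 9 stages was 18509, and the highest count over 99 random assignments of the libraries to stages was 2620. The real split was the only 1 of 100 to reach its count, so a random assignment is an unlikely source of it. As lane pair follows stage outside F41, this does not tell the stage from the lanes. The contrasts of 3 libraries against 3 allow 10 splits, too few for a share under 5%. Real and highest other counts were 10823 and 0 for F34 vs F8, 13123 and 18 for F53 vs F41, 4146 and 0 for F15 vs F8, 984 and 0 for F21 vs F15, 4 and 1 for F28 vs F21, 2 and 0 for F34 vs F28, and 87 and 32 for F53 vs F50. For concentrations they were 19365 and 1 for F34 vs F8, and 4456 and 19 for F53 vs F41. In F41 vs F34, 4 of 10 splits called at least the 5 genes of the real one, and the split that set F41 replicates 2 and 3 with F34 replicate 1 against the rest called 304, which points to a structure of the samples that follows F41 replicate 1.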
